A study of Danio rerio with 4 samples.

How the data were processed

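Whole zebrafish embryos at 15 hpf were cross-linked, and sonicated chromatin was immunoprecipitated with an antibody against GFP in 2 libraries, with 2 input libraries without antibody, per the labels' protocols. The groups follow the library titles. The submitters' processing notes name BWA 0.1.17, MACS2 2.2.6, deepTools 3.5.1 and the assembly GRCz11, without their roles, order or settings. BWA is a read aligner, MACS2 a peak caller and deepTools a suite for coverage tracks.

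The authors deposited 1 headerless list for the series, with 1 line of 1 bp per peak summit, a region name and a −log10 score. Letters after a region's number mark several summits in one region. Every line carries the same run name, no region number is missing and no position occurs more than once. The deposited −log10 values have a minimum of 1.30158, just above 1.30103, the −log10 of 0.05, so they were read as −log10 q-values kept at a q of 0.05 or less. A threshold of 0.05 on p-values without correction could give the same minimum, so this reading is an inference. With either reading the score rises with the depth of sequencing as well as with enrichment, and it is the peak caller's own value for a summit. Whether the 2 ChIP libraries were pooled before calling, which control was used, and how reads that match several places were treated are not given in the sources used here. The last of these affects repeated sequence most. No peak widths, heights or fold enrichments were used, since each line gives a summit only, and there were 0 other columns of per-sample values.

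Several parts of the plan fixed before the data were examined were not run. Promoter and gene feature shares, distances to transcription starts, 26 binding motifs including that of GFI1 proteins, 18 gene lists, the cebpa locus and repeat content all need the GRCz11 sequence or its gene annotation, which were not used here. The gene table at hand belongs to the assembly GRCz12tu, and positions were not converted between assemblies. The planned comparison of ChIP with input libraries needs values per library. The rule for named genes took a fixed set of regulators, the genes at the strongest promoter peaks, members of the gene lists and the 5 strongest peaks. Only the last part could be applied, and it is given as positions. All descriptions of spacing, chromosome ends, chains of summits and scaffolds were chosen after the data were seen. The density per chromosome was planned against sequence length without unresolved bases and is given against the distance from the first to the last summit of each chromosome.

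Positions are 1-based. Densities per chromosome were compared with their share of the summed span by exact binomial tests with 95% Clopper-Pearson intervals, which cover counting error only and are too narrow for clustered summits. Full 5 Mb windows were therefore permuted 100000 times between chromosome 4 and the rest. That test still takes neighbouring windows as independent and makes no allowance for the choice of the sparsest chromosome. Gaps between regions were measured between their strongest summits and compared with 1000 random placements of as many positions on the same chromosomes. Chromosome ends were taken from the first and last summit, with that summit left out, and the log2 ratio of the outer 500 kb to the rest was tested by 100000 random sign flips. Shares among the strongest summits were tested by Fisher's exact test with 95% conditional intervals for the odds ratio. Medians have percentile intervals from 1000 bootstrap draws over summits, or over loci for the summits around the strongest ones. Gaps among the top 10% of regions were also compared with 1000 random sets of regions. Empty windows on chromosome 4 were compared with those of each other chromosome after regions were removed at random to the same mean number of summits per window (100 draws). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

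The statistics were tested on simulated data with the real chromosome spans and 109722 regions. Random positions gave a 1.00-fold share of gaps under 5 kb, and moving 30% of the regions beside another gave 1.46-fold. A 1.5-fold excess put into the chromosome ends (110720 positions) was found as a median ratio of 1.47, and no excess as 1.02. These positions were independent of each other, whereas the main test of the ends used all summits, which cluster. The simulation therefore does not show how clustering, or stretches without sequence, affect that ratio. A correlation of 0.3 put into the scores of neighbouring regions was found as 0.281, and none as 0.0031. Alternatives were the top 50% and top 10% of summits, merging of summits closer than 500 bp, 1 summit per region, other window lengths, leaving out chromosome 4, and placement within 1 Mb windows.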

Results

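Chromatin bound by Gfi1aa, a zinc finger transcriptional repressor that acts in blood development, was profiled in whole zebrafish embryos at 15 hours post fertilisation (hpf). Chromatin immunoprecipitation with an antibody against GFP was sequenced from 2 libraries, alongside 2 input libraries made without an antibody. No library made with the antibody from embryos without GFP is among them. Background of the antibody therefore cannot be told apart from binding of Gfi1aa. The labels do not say how GFP was joined to Gfi1aa, nor whether the libraries came from separate clutches. The question was where Gfi1aa binds in the genome. The processed data consisted of 1 list of peak summits for the whole series on the GRCz11 assembly, with a score per summit read as −log10 of its q-value. Enrichment was therefore scored once, with no value per library, so no summit has a replicate error and the background of the input libraries cannot be shown beside it. The spreads given below are spreads between chromosomes, chromosome ends or windows of the genome. The number of reads per library is not given in the sources used here, and the depth behind each score is therefore unknown. Genes were not assigned to summits, because no GRCz11 gene annotation was used here, and the occupancy of cebpa, the myeloid transcription factor gene named by the study, was not analysed here.

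Anti-GFP enrichment was called at many places on every chromosome. The list held 163838 summits in 111166 peak regions. Of these, 161735 summits (98.7%) lay on chromosomes 1 to 25, 2079 (1.27%) on 528 unplaced scaffolds and 24 on the mitochondrial genome. Scores were strongly skewed. The median score was 7.29, with quartiles of 3.74 and 16.97, and the smallest was 1.302. Raising the minimum score to 5 left 105989 summits, a minimum of 20 left 34640, a minimum of 100 left 3317, and a minimum of 1000 left 18. Many low scores were shared by many summits: the 20 most frequent values, from 1.43 to 10.8, held 24.6% of all summits and 38.9% of the 103489 summits scoring up to 10.8.

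The strongest enrichment was concentrated in a few short stretches. The highest score, 55147, stood at a single summit on chromosome 8 at position 4797930, 4.58 times the next one. That next summit lay on chromosome 2 at position 10776587, with a score of 12034, and 2 further summits above 1000 flanked it within 7.57 kb, at 10779613 (4376) and 10772039 (1510). The fourth strongest summit was on chromosome 11 at position 15114724 (3855), and the fifth was on an unplaced scaffold (2982). The 18 summits scoring 1000 or more formed 10 loci when those within 50 kb were joined, 7 on chromosomes and 3 on unplaced scaffolds. The other chromosomal loci were on chromosome 24, where 3 such summits spanned 47.1 kb from position 12369244 to 12416325, on chromosome 4 at 61736882, on chromosome 10 from 44664086 to 44664353, and on chromosome 16 at 15658491. Whether any of these stretches, those on chromosomes 8 and 2 included, is also carried by the construct that supplied GFP was not analysed here.

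**Figure D1:**
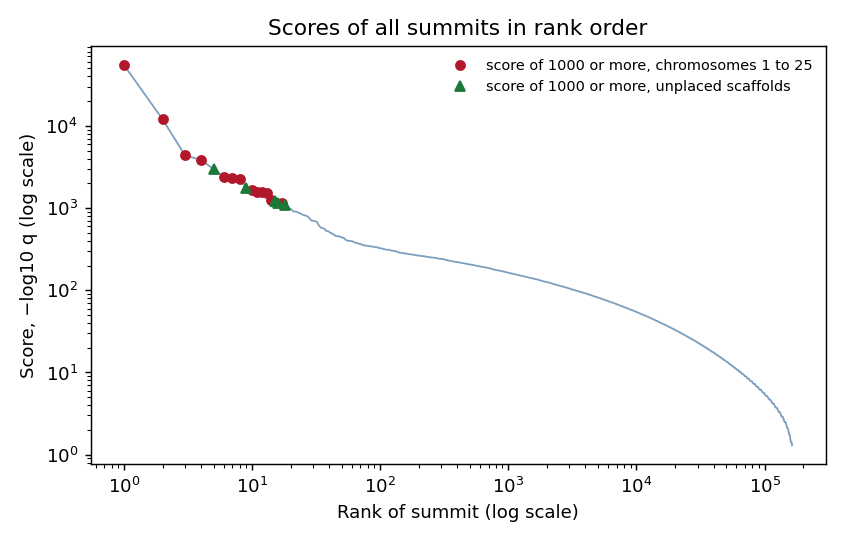
Score of every summit (read as −log10 q, log scale) against its rank (log scale), with the 13 summits of 1000 or more on chromosomes 1 to 25 as circles and the 5 on unplaced scaffolds as triangles. The first summit, at 55147, stands 4.58 times above the second, and the median of all summits is 7.29.

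Unplaced scaffolds were over-represented among the strongest summits. They held 15 of the 164 summits in the top 0.1% of scores (9.15%) against 1.26% of all others, an odds ratio of 7.88 (95% interval 4.30 to 13.5, Fisher's exact test, two-sided, p = 3.83e-09). In the top 1% the odds ratio was 1.76 (p = 0.00176, Fisher's exact test), and in the top 10% the excess no longer passed the test, with an odds ratio of 1.14 (p = 0.0659). Summits of one region are not independent, so these intervals cover counting error only.

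Several summits often stood side by side. On chromosomes 1 to 25, 30731 of 109722 regions (28.0%) held more than 1 summit, and adjacent summits of a region were a median of 566 bp apart (quartiles 400.0 and 775 bp). Regions with several summits had higher scores. The median score of the strongest summit was 6.59 in regions with 1 summit, 12.0 with 2, 19.1 with 3, 28.9 with 4 and 48.2 with 5 or more. A maximum over more summits is higher by construction, and the median summit of a region gave a smaller and uneven rise, with medians of 6.59, 8.73, 8.39, 11.1 and 12.9 for the same classes. By the strongest summit, regions with several summits had the higher median on 25 of 25 chromosomes (ratios of 2.104 to 2.77, exact sign test, two-sided, p = 5.96e-08). Having more summits favours that direction in advance, so this test is no separate evidence. With the median summit of each region in place of the strongest, the ratio of the medians fell from 2.36 to 1.38, and the direction held.

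The most extended enrichment was a chain of 60 summits on chromosome 1, from position 45570951 to 45612749 (41.8 kb). Its strongest summit scored 128 and its median summit 18.6. The next longest chains by number of summits were 32 summits on chromosome 15 (20901368 to 20921377, 20.01 kb), 30 on chromosome 17 (43849226 to 43867828, 18.6 kb), 29 on chromosome 14 (12150640 to 12168241, 17.6 kb) and 29 on chromosome 22 (18729671 to 18749519, 19.8 kb). Of the 109722 chromosomal regions, 204 held at least 10 summits, spread over 25 chromosomes, and 14 held at least 20. The chain on chromosome 14 peaked at a score of only 29.7, whereas that on chromosome 17 reached 193.

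Over all regions, short gaps between regions were more frequent than between random positions, and so were long ones. Of the gaps between neighbouring regions, each placed at its strongest summit, 45.8% were shorter than 5 kb, against 33.6% ± 0.119 (SD, n = 1000 random placements on the same chromosomes), a 1.36-fold excess (permutation p = 0.002, two-sided, the smallest these draws can give). The excess was 2.097-fold among the top 10% of regions by score. With each region moved only within its own 1 Mb window it was 1.26-fold. Gaps longer than 50 kb made up 3.93% against 1.73% in the random placements, a 2.27-fold excess. That excess was absent in the top 50% of regions by score (1.01-fold, permutation p = 0.166, two-sided). In the top 10% such gaps were fewer than in random placements (0.785-fold). Stretches of the assembly that hold no sequence could not be left out of the placements. In windows of 100 kb, the variance of the number of regions was 3.46 times its mean. For summits, of which several can belong to one region, it was 7.35 times the mean, with a range of 0 to 74 and a median of 10.

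Summits were sparser on chromosome 4 than on any other chromosome. Its density was 90.1 summits per Mb between its first and last summit, against 122 ± 6.31 (SD, n = 24 other chromosomes, range 112 to 137). Its share of the summits was 0.749 of its share of the summed span (95% exact binomial interval 0.732 to 0.766, for counting error only). In full windows of 5 Mb, chromosome 4 averaged 88.9 summits per Mb over 15 windows, against 122 ± 32.5 over the 242 windows of the other chromosomes (permutation of windows, two-sided, p = 6.0e-04). Neighbouring windows resembled each other and chromosome 4 was taken as the sparsest chromosome, so this p-value overstates the evidence. Chromosome 23 had the highest density, 137 summits per Mb, and chromosome 13 followed with 133.

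**Figure D2:**
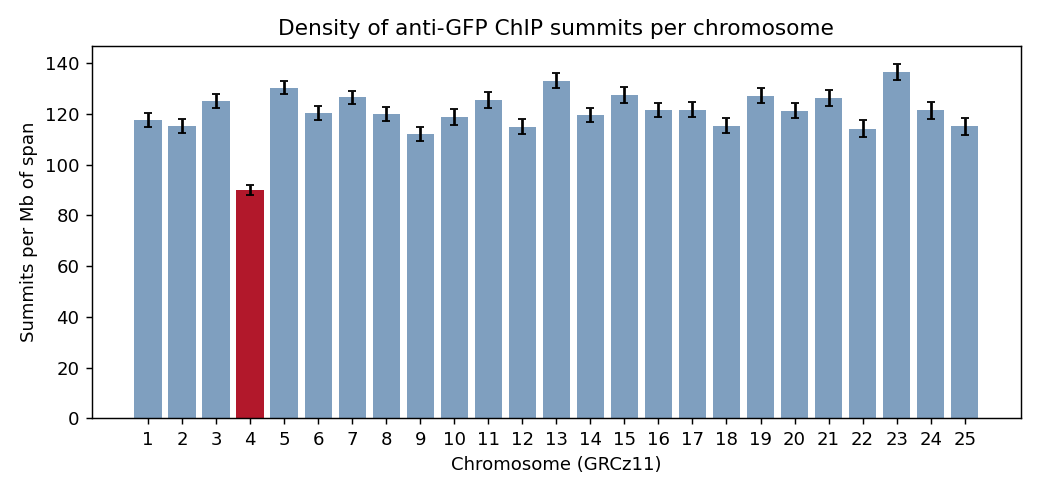
Summits per Mb of span (y axis) on each of the 25 chromosomes (x axis); error bars are 95% exact binomial intervals of the chromosome's share of summits, for counting error only. Chromosome 4, in red, is at 90.1 summits per Mb, below the 112 to 137 of the others.

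The deficit on chromosome 4 was limited to one part of it. Up to position 30 Mb, a boundary chosen after the windows were seen, it held 175 summits per Mb, and its 6 windows ranged from 105 to 223 summits per Mb. Beyond 30 Mb it held 1782 summits in 48.0 Mb, or 37.1 per Mb, and its 9 full windows ranged from 22.2 to 60.0 per Mb. Of those 9 windows, 8 were below the lowest of the 242 windows on other chromosomes, which held 49.8 per Mb. The stretch after 75 Mb lies in no full window. The outer 500 kb at that end held 106 summits per Mb, so the sparse part stopped short of the far end. The summits called beyond 30 Mb, which are those that passed the threshold of the list, had a median score of 8.11 (95% bootstrap interval 7.71 to 8.64) against 7.29 on the other chromosomes. This part held 10 of the 164 summits of the top 0.1% (6.10%) against 1.08% of all others (odds ratio 5.93, Fisher's exact test, two-sided, p = 1.46e-05); the odds ratio fell to 1.71 in the top 1% (p = 0.00779) and 1.17 in the top 10% (p = 0.0354). The longest gap between neighbouring regions on chromosomes 1 to 25 also lay there, 919 kb from position 45543850 to 46462489.

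**Figure D3:**
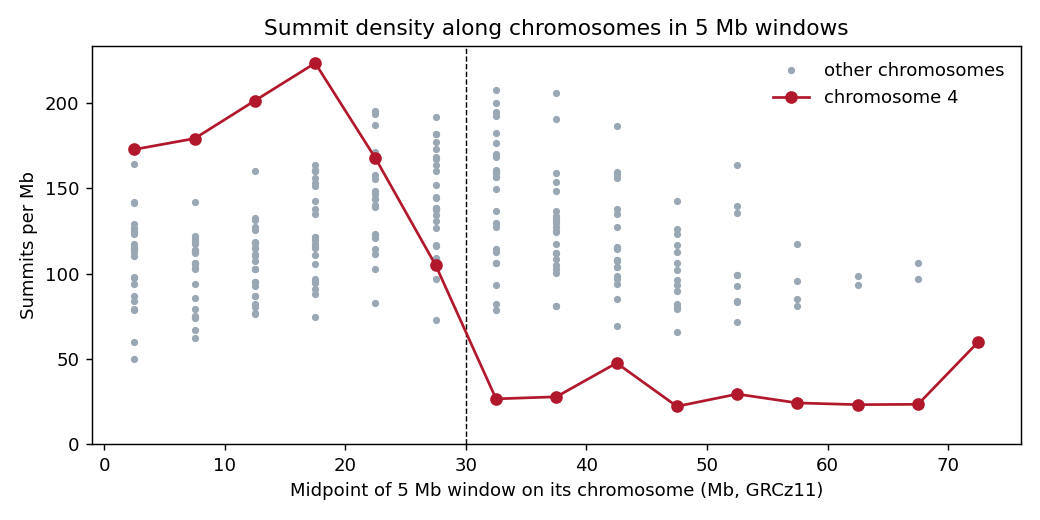
Summits per Mb (y axis) in full 5 Mb windows by position on the chromosome (x axis, Mb); red points joined by a line are chromosome 4, grey points the other 24 chromosomes, and the dashed line marks 30 Mb. Chromosome 4 falls from 105 to 223 summits per Mb before the line to 22.2 to 60.0 in the full windows beyond it. Its stretch after 75 Mb fills no window and is not drawn.

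Summits were denser in the outer 500 kb of chromosomes than in the rest. The outer 500 kb of the 50 chromosome ends held 177 ± 56.0 summits per Mb (SD, n = 50 ends), against 120 ± 8.85 (SD, n = 25 chromosomes) in the rest of the same chromosomes. The median ratio was 1.45 (quartiles 1.16 and 1.87), and 43 of 50 ends were denser than their own chromosome (sign-flip permutation test on log2 ratios, two-sided, p = 1e-05, the smallest these draws can give). Both ends of a chromosome were divided by the same density of its rest. The test took the 50 ratios as independent, so this p-value may overstate the evidence. The largest ratio was at the start of chromosome 4, with 286 summits per Mb against 88.7, a value lowered by the sparse part beyond 30 Mb; up to 30 Mb the chromosome held 175 per Mb. The next largest was 2.33, at the start of chromosome 14 (274 against 118). The lowest ratios were at the start of chromosome 7 (74.0 against 126) and at the far end of chromosome 20 (72.0 against 122). Counting 1 summit per region gave a median ratio of 1.302 with 39 of 50 ends denser. The median ratio was 1.56 for the outer 250 kb and 1.25 for the outer 1 Mb, so the excess faded inwards. It did not extend over the first 5 Mb of most chromosomes. Those windows ranged from 49.8 summits per Mb on chromosome 7 to 172.8 on chromosome 4. Most were sparser than their whole chromosome, such as 59.8 against 125 on chromosome 3 and 79.0 against 122 on chromosome 17. A minority were denser, such as 164 against 121 on chromosome 24.

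**Figure D4:**
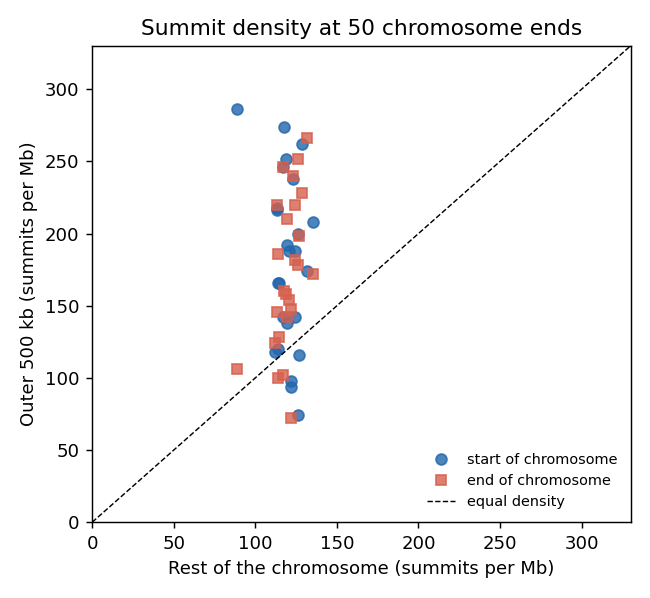
Summits per Mb in the outer 500 kb (y axis) against the rest of the same chromosome (x axis) for 50 chromosome ends; circles are chromosome starts, squares the far ends, and the dashed line marks equal density. Of the 50 ends, 43 lie above the line.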

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

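All tests in this part were chosen after the patterns they bear on were seen, and only the limits of the first test of long segments and of both tests on chromosome ends were set before the values these measure were seen. The count used for a few unusual ends follows by subtraction from the pattern itself. That test is therefore no separate evidence. Samples of different groups cannot be compared in this list, so no biological explanation was tested.

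The mitochondrial genome and the unplaced scaffolds stand outside the comparisons by chromosome and also carry summits. The mitochondrial genome held 24 summits from position 406 to 16155, with a median score of 11.9 against 7.29 in the whole list. Its density was 1460 summits per Mb of that span, against 90.1 to 137 per Mb on the chromosomes. Whether these summits are background of the antibody was not tested. Unplaced scaffolds held 2079 summits with a median score of 7.82.

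The first pattern is the set of 18 summits with scores of 1000 or more, led by those on chromosomes 8 and 2. Extra copies of a long segment were taken to predict raised scores around. Input libraries would carry such copies too, and which control was used is not given, so scores need not rise. A first test resampled summits, the 50 others 5 to 50 kb from the bounds of the 7 chromosomal loci. Their median was 11.4 (interval 7.27 to 18.2), 1.57 times that of all chromosomal summits. The upper bound was under the 3 times (21.9) below which the explanation had been set to fail. That test took summits of only 7 loci as independent. After its values were seen it was therefore changed to distances from the nearest such summit and to resampling of loci. This gave 1.66 with an interval of 7.26 to 37.1 in score. All of it lay below the 10 times (72.9) that the explanation was set to need, but not all below 3 times. With the control unknown, this pooled median does not decide on the explanation. In the changed test the medians by locus were 2.71 on chromosome 4, 6.74 on chromosome 16, 7.54 on chromosome 8, 10.6 on chromosome 10, 14.3 on chromosome 2, 37.1 on chromosome 24 and 74.6 on chromosome 11. Only the last of these, from 16 summits, was above the 72.9 set as needed. The pooled median therefore does not speak for that locus. Collapsed sequence, and short extra copies of a few kilobases such as those of an introduced construct, were not tested and stay open, for the loci on chromosomes 8 and 2 as for the rest.

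The second pattern is the low density on chromosome 4 beyond 30 Mb. Whether weaker enrichment left summits under the threshold of the list cannot be read from it, since it scores only those that passed. Stretches in which reads cannot be placed uniquely could leave windows empty. Of the 480 windows of 100 kb in this part, 19.4% held no summit. The exact 95% interval, for counting error only, starts at 15.9%. With regions removed at random down to the same mean, each of the 24 other chromosomes had a lower share. Those shares averaged 15.7% ± 0.906 (SD, range 14.0% to 17.7%). Only the mean was matched, and density beyond 30 Mb was uneven. It was 22.2 to 60 summits per Mb in the longer full windows and 106 in the outer 500 kb. Such unevenness can by itself leave more windows empty at the same mean, so the excess does not decide on this explanation. The explanation was also set to need a median of at least 10 in the windows with a summit, as in all windows of other chromosomes, and they held 3, near the 3.075 to 3.425 of the thinned chromosomes, so the low mean alone gives such a value. Unplaceable reads and closed chromatin in this part cannot be told apart without the sequence and the coverage of the input libraries.

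The third pattern is the excess of summits in the outer 500 kb of chromosomes. A few unusual ends are argued against by the 43 of 50 ends that were denser than their chromosome; leaving out the 5 ends with the largest ratios, all among these, leaves 38 of 45 by subtraction, and the median ratio of those left was 1.36. Collapsed repeats that raise scores near the ends were set to give a higher median score there, and it was 7.61 against 7.27 in the rest. The lower bound of its interval, 7.29 to 7.89, only just exceeds the value of the rest. That interval took 4477 summits as independent although they come from 50 ends, so it is too narrow to decide. Gene density and base composition were not tested.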

How the results depend on the processing

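All alternatives were added after the data were seen, except the score thresholds, merging and chromosome choice for the number of summits, and the score thresholds for chromosome 4. The top 50% by score holds 82025 summits and the top 10% 16387, by construction; merging summits closer than 500 bp left 142705. Chromosome 4 stayed below its share in 4 of 4 alternatives (0.713 to 0.750). The excess of gaps under 5 kb held in 4 of 4 (1.26 to 2.097) and that at chromosome ends in 6 of 6 (1.25 to 1.56). Regions with several summits kept the higher median in the 1 alternative (1.38-fold). The excess of scaffolds held in the top 1% and lost significance in the top 10%, with an odds ratio of 1.14; the cause was not tested. The settings listed beforehand for promoters, gene features, motifs, gene lists, the cebpa locus and repeats were not run. No paired analysis was possible because the list gives no value per library, and for the same reason no replicate could be left out. Unknown depth limits every score.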

Other observations

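All tests in this part, and the limits they were held to, were chosen after their results, or results that nearly fix them, were seen. Some stretches of 100 kb were crowded with summits. The fullest, on chromosome 3 from 23700001 to 23800000, held 74 summits with a median score of 19.2. Next came chromosome 16 from 7700001 to 7800000, with 71 summits and a median score of 6.21, chromosome 14 from 24300001 to 24400000, with 70 summits and 7.76, and chromosome 16 from 29500001 to 29600000, with 70 summits and 10.3. Over the 10 fullest windows the median scores ranged from 6.21 to 19.2, against 7.29 in the whole list. In all, 50 of 13433 such windows held at least 50 summits, and 371 held none, 96 of them on chromosome 4.

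Crowding raises the hypothesis that strong regions sit in domains of strong enrichment. Among the top 10% of regions by score, 8.52% of gaps were under 5 kb, against 5.64% ± 0.204 (SD, n = 1000) in random sets of as many regions per chromosome, a ratio of 1.51 (permutation p = 0.002, two-sided, the smallest these draws can give). Against the highest random set, 6.34%, the ratio was 1.34, under the limit of 1.5, so the test does not decide. Over all regions the scores of neighbours were correlated only weakly, with a Spearman rho of 0.0548 over 109697 pairs (95% interval 0.0491 to 0.0608 from resampling chromosomes), against a highest value of 0.00941 in 1000 shuffles within chromosomes, and the correlation was positive on 25 of 25 chromosomes. Regions are not independent replicates. The strongest regions lay closer together than random sets of regions, which leaves open whether they sit in domains; extra copies of sequence and one enriched stretch called as several regions were not tested.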
